A study of Mus musculus with 11 samples.

How the data were processed

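Poly(A) RNA was profiled by RNA sequencing in 11 libraries, each from the nucleus accumbens shell of 1 mouse aged 8 weeks. Per the labels' protocols, the tissue was punched from frozen brain sections of 300 µm, and libraries were made from 200 ng of total RNA with a stranded TruSeq mRNA kit and 12 PCR cycles. The series design names 12 samples and says that 1 of them failed quality control. The labels give each library an animal code and no genotype, so all libraries were left without a group and no comparison between groups was made.

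The deposited table holds raw counts of reads per gene, made by the authors and not normalized. Per the submitters' processing notes, bcl2fastq 2.17.1.14, TopHat2 2.0.14, Bowtie2 2.1.0 and HTSeq 0.6.1 were used with the mm10 genome. The strand setting of the counting and the release of the annotation are not given in the sources used here, so genes with an antisense partner or an overlapping gene are uncertain, as are near-identical copies and pseudogenes. The table pairs counts with gene identifiers, of which 52403 of 52550 matched GENCODE M21, the source of names, coordinates, lengths and GC content. The 147 without a match held 0.0112 to 0.0214% of the counts of a library. A later annotation than the one used for counting can give a gene other limits.

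Counts normalized to library size in the usual CPM unit were computed from the deposited counts on library sizes scaled by the trimmed mean of M values in edgeR 4.0.16 (R 4.3.3), with factors from 0.908 to 1.06. Library totals ran from 24840981 to 48825783 counts, so 3 counts, used as the floor, corresponded to 0.0619 to 0.133 CPM. Genes with at least 1 CPM in 3 libraries and a median count of at least 10 were kept for measures of spread. The spread of a gene is its biological coefficient of variation from edgeR, fitted with an intercept only and without sharing between genes, and it holds genotype, animal, dissection and library differences together. A gene list was described by the median spread of its members, as a percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. The list score of a library is the mean over members of log2(CPM + 0.5) after subtraction of each gene's median. Log2 values from the authors were not used.

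Relations over the libraries were tested two-sided with Pearson's r and Spearman's rho by 100000 permutations, with Benjamini-Hochberg adjustment within each family, and r was computed again without the 2 libraries farthest from the median of the first measure. The smallest p these permutations can give is 1e-05. Values were said to fall into separate clusters when the largest gap between neighbouring values was over 0.5 of the range with at least 2 libraries on each side, and then no r over all libraries is given. For genes a log2 range of at least 1 was also required. Principal components were taken from the 500 genes of highest variance. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps, and DESeq2 1.42.0 for alternative size factors. No labelled sequencing batch was found, so no relation could be computed within batches. The sample descriptions give each library a numbered code, from NSZR1 to NSZR14. What the numbers stand for is not given, so an order or batch behind them is unknown.

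The 34 gene lists, the relations, the alternatives and the rule for naming genes were set before the data were examined. The lists cover striatal projection neurons (all, direct and indirect pathway), striatal genes of Huntington disease models, retinoid machinery and retinoic acid induced genes, ventral and dorsolateral striatum, cholinergic and GABAergic interneurons, astrocytes, oligodendrocytes and their precursors, microglia, vessels, red blood cells, choroid plexus and ependyma, cortical and septal or diencephalic neurons, and the subventricular zone. They also cover immediate early, glucocorticoid, clock, mitochondrial, ribosomal, interferon and heat shock genes, RNAs without a poly(A) tail, sex-linked and strain-variable genes, neighbours of Rarb, and Htt with its partners. Named genes are Rarb, Htt, Drd1, Drd2 and the retinoid genes, the 10 most abundant genes, the 25 of largest and 5 of smallest spread, the most abundant, most and least variable members of each list, up to 4 more members of the 6 lists of most spread, the 5 leading genes of each end of the first 2 components, the sex-linked, strain-variable and Rarb neighbour lists, and the 20 most abundant genes in separate clusters. Parent genes of copies and Hap1, Ttr, Fos, Arc, Hba-a1, Hspa1a, Ier5l, Hmga1b and Gm9825 lie outside that rule and were named after their values were seen.

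The spread and cluster steps were tested on simulated data with the real means and library sizes of 15373 genes. Of 200 genes given a spread of 0.8 the median estimate was 0.769 and 95.5% reached 0.5, against 0.00668% of genes given 0.2, whose median estimate was 0.193. Separate clusters were called for 35.0% of 200 genes with a split of 2 on the log2 scale and for 0.0868% of the others. The relation step was tested on normal random values, 1 per library, and not on counts or list scores. Of 200 unrelated pairs 4.0% had p at or below 0.05, and of 200 pairs with a correlation of 0.9, 99.5% did. These rates do not cover list scores that share a gradient over the libraries. Alternatives were unscaled totals, DESeq2 size factors, other dispersion estimates, other filters and pseudocounts, medians or unit variance over list members, a wider gap for clusters and each library left out. Removal of each library's trend with GC content or length, a smaller gap for clusters, and a length measure without the members of a list beside random lists of the same transcript lengths were added after the data were seen.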

Results

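RNA from punches of the nucleus accumbens shell, a ventral part of the striatum, was profiled in 11 libraries from mice aged 8 weeks on a mixed CBA/C57BL6J/129svEmx background. The series asked how weaker signalling through Rarb, a retinoic acid receptor, alters transcription when a mutation that causes Huntington disease is present. R6/1 mice carry a fragment of the human huntingtin gene with an expanded CAG repeat. The labels used here name each library by an animal code and give it no genotype. All 11 libraries were therefore left unassigned, no groups were compared, and values are given per library or as the median and range over the 11.

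Between 24840981 (m61) and 48825783 (m49) reads were assigned to genes, with a median of 36252983. A count above 0 was found for 20524 genes in m61 and for 24952 in m57. Transcripts of the mitochondrial genome took 2.90% of the counts in m74 (95% Wilson interval 2.90 to 2.91%) and 7.21% in m61 (7.20 to 7.22%). These intervals treat every read as independent and leave out differences between animals and libraries. Reads amplified by PCR are not independent molecules, so the intervals may be too narrow even for counting error. The most abundant genes were mt-Cytb, with a median of 9408 CPM (counts normalized to library size, as given in the processing section), mt-Co1 (7691 CPM) and mt-Nd1 (5728 CPM). Among nuclear genes the lincRNA Meg3 (3388 CPM) and Lars2 (2876 CPM) had the highest medians. Whether all reads counted for Lars2 came from its transcript was not tested. Meg3 ranged from 1081 CPM in m61 to 4380 CPM in m101, and its spread of 0.334 became 0.153 without m61. No pair of libraries matched within counting noise, since the lowest chi-square per gene between any pair was 16.0.

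Rarb (ENSMUSG00000017491, chromosome 14, 16430839 to 16819156, minus strand, mm10) was detected in every library, with a median of 72.9 CPM. Rarb ranged from 49.8 CPM in m74 to 101.2 CPM in m44, a ratio of 2.03. The values were 79.1 CPM in m115, 64.7 in m49, 80.4 in m47, 63.0 in m73 and 65.6 in m101. They were 72.9 CPM in m61, 90.1 in m89, 67.9 in m83 and 93.5 in m57. The biological coefficient of variation, called spread below, was 0.203 for Rarb (0.168 to 0.213 with each library left out), near the median of 0.201 over all genes tested. Without scaling of library sizes the median was 68.5 CPM. Because the labels do not say which mice carried the altered allele, or which part of the gene was altered, the Rarb level could not serve as a check of the labels.

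Htt, the mouse huntingtin gene (chromosome 5, 34761740 to 34912534), had a median of 139 CPM and ranged from 100.3 CPM in m61 to 183 CPM in m57, with a spread of 0.180. The list of Htt, its partners and BDNF signalling genes had a median spread of 0.191, at percentile 50.6 of 10000 random gene lists of the same size and expression. Hap1, which codes for a huntingtin partner, lay between 262 and 515 CPM. Ntrk2, the BDNF receptor gene, lay between 371 and 646 CPM. Bdnf itself was low (median 6.61 CPM) and had the largest spread of this list, 0.390.

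Among the other retinoid receptors, Rxrb (median 85.6 CPM), Rxra (36.1 CPM), Rarg (15.3 CPM) and Rara (10.5 CPM) varied little, with spreads from 0.116 to 0.140. Rxrg, the retinoid X receptor of striatal neurons, varied more (35.4 to 79.2 CPM, spread 0.274) and was highest in m83. Of the 19 measured genes for retinoid receptors, binding proteins, synthesis and breakdown, 15 passed the expression filter. As a list their median spread of 0.281 lay at percentile 98.2 of the random lists, which was 92.9 without m73 and 94.8 without m83. Dhrs3, a retinal reductase, had the largest spread among those past the filter, 0.4003, from 9.69 CPM in m47 to 28.4 CPM in m83. Aldh1a1, which makes retinoic acid, ranged from 11.3 to 37.1 CPM. Stra6, the receptor for retinol binding protein, ranged from 9.02 to 26.8 CPM, Rbp4 from 8.32 to 21 CPM and Rdh10 from 9.48 to 16.6 CPM. Crabp1 had a median of 3.46 CPM and Cyp26b1, a retinoic acid hydroxylase, of 2.20 CPM. Aldh1a2 (0.845 CPM), Aldh1a3 (1.09 CPM) and Crabp2 (0.441 CPM) were near or below 1 CPM. Cyp26a1 (median 0.125 CPM) and Cyp26c1 (at most 0.0313 CPM) were at or near the floor of 3 counts, which was 0.0619 to 0.133 CPM in these libraries. The 7 retinoic acid induced genes past the filter had a median spread of 0.321, at percentile 98.8, with a list score from −0.54 in m73 to 0.53 in m44.

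**Figure D1:**
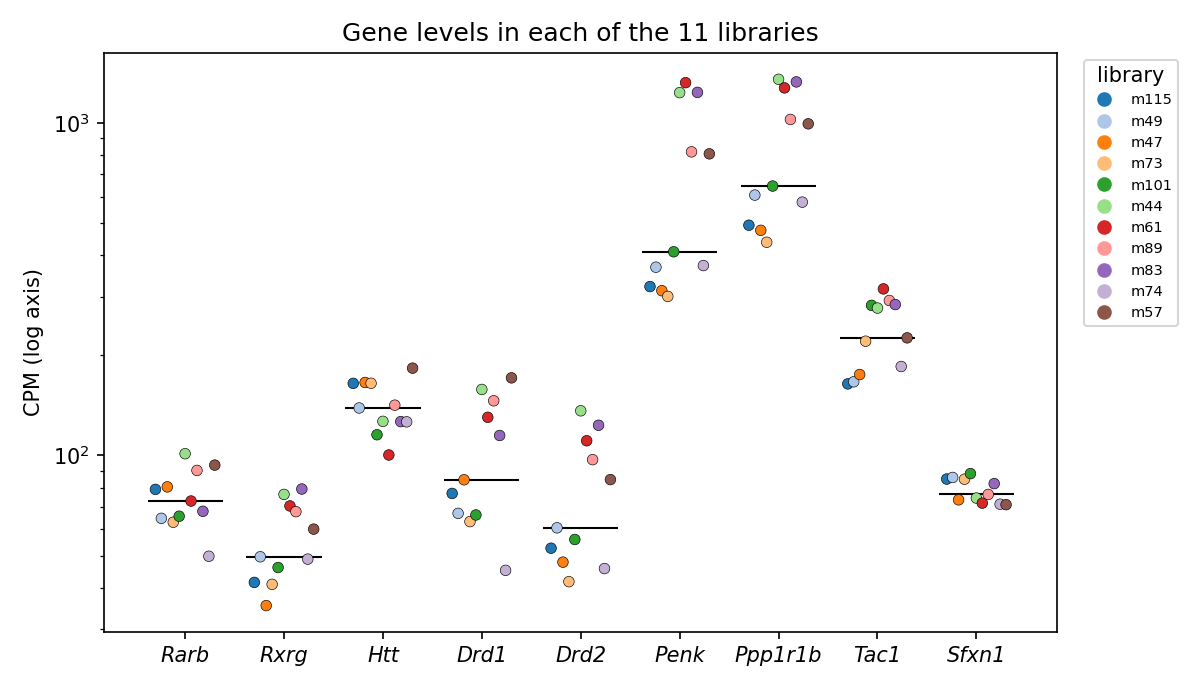
Level of 9 genes in each library, in CPM on a log axis. Each point is 1 library, its colour gives the animal code, and the horizontal line is the median over the 11 libraries. Sfxn1 stayed between 71.1 and 88.2 CPM, whereas Penk ranged from 301 to 1321 CPM.

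Genes of the striatal projection neurons, the main cell type of this region, varied between libraries far more than random lists of genes at the same expression. The 12 genes common to these neurons had a median spread of 0.357 against 0.161 in the random lists, at percentile 100. Their list score, the mean log2 deviation from each gene's median, ranged from −0.51 in m74 to 0.65 in m44. Pde10a, a striatal phosphodiesterase, had the largest spread (0.599), from 68.9 CPM in m49 to 486 CPM in m57. Ppp1r1b, which codes for DARPP-32, ranged from 438 CPM in m73 to 1352 CPM in m44, and Gng7, a G protein subunit gene, from 478 to 990.0 CPM. Bcl11b, a transcription factor of these neurons, had the smallest spread of the list, 0.161, which became 0.103 without m74.

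The indirect-pathway genes had the largest median spread of the 34 lists, 0.540 over 5 measured members, at percentile 100. Penk, the enkephalin precursor gene, ranged from 301 CPM in m73 to 1321 CPM in m61. Adora2a, the adenosine receptor gene, ranged from 52.4 to 209 CPM, and the orphan receptor gene Gpr6 from 14.7 to 53.0 CPM. Drd2, the dopamine D2 receptor gene, had a median of 60.6 CPM and ranged from 41.7 CPM in m73 to 136 CPM in m44, with a spread of 0.426. Sp9, a transcription factor of the same cells, had a smaller spread (0.209; 16.1 to 29.3 CPM).

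The 9 direct-pathway genes had a median spread of 0.299, at percentile 99.6. Drd1, the dopamine D1 receptor gene (chromosome 13, 54051183 to 54055705), had a median of 84.5 CPM and ranged from 45.1 CPM in m74 to 171 CPM in m57, with a spread of 0.428. Tac1, the substance P precursor gene, ranged from 164 to 317 CPM, and Pdyn, the dynorphin precursor gene, from 123 to 311 CPM. Sfxn1 had the smallest spread of the list, 0.0817.

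A list of 18 striatal genes known to fall in Huntington disease models was fixed beforehand, and all 18 had a spread above the median of all genes. Their median spread was 0.432, at percentile 100. Scn4b, a sodium channel beta subunit gene, had the largest spread of the list (0.799), from 69.0 CPM in m73 to 475 CPM in m44. Hpca, the hippocalcin gene, was the most abundant member (572 to 1382 CPM), and Actn2 had the smallest spread (0.228). Arpp21 ranged from 417 to 1151 CPM, Adcy5 from 300.4 to 836 CPM and Rgs4 from 177 to 455 CPM. This list shares members with the lists of the projection neurons, so their spreads are not independent.

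Genes enriched in the ventral striatum had a median spread of 0.351, at percentile 99.97, and their score ranged from −0.81 in m74 to 0.68 in m44. Nnat was the most abundant (314 to 772 CPM), and Calcr, the calcitonin receptor gene, had the largest spread, 0.812, from 0.367 CPM in m74 to 10.3 CPM in m115. Stard5 had the smallest (0.210). Genes enriched in the dorsolateral striatum lay at percentile 89.9, with Cnr1, the cannabinoid receptor gene, between 61.4 and 236 CPM and Reln between 23.1 and 42.0 CPM.

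Cholinergic neuron genes had a median spread of 0.397, at percentile 99.4. Slc5a7, the choline transporter gene, ranged from 3.92 CPM in m74 to 23.3 CPM in m57, Ecel1 from 17.8 to 57.02 CPM and Zic4 from 2.62 to 5.21 CPM. GABAergic interneuron genes had a median spread of 0.266, at percentile 99.3. Sst, the somatostatin gene, ranged from 159 to 406 CPM and Vip from 5.34 CPM in m115 to 29.1 CPM in m61, while Lhx6 varied less (spread 0.160).

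Myelin genes of mature oligodendrocytes had a median spread of 0.306, at percentile 100, with a score from −0.57 in m47 to 0.58 in m83. Mbp, the myelin basic protein gene, ranged from 836 to 2178 CPM, Ugt8a from 11.2 to 34.9 CPM and Ermn from 19.6 to 40.3 CPM. Precursor genes of this lineage lay at percentile 90.6, with Tnr between 116 and 269 CPM, Enpp6 between 3.32 and 8.35 CPM and Olig2 at a spread of 0.117. Astrocyte genes lay at percentile 70.9, or 46.97 without m74. Slc1a2, the astrocytic glutamate transporter gene, ranged from 1002 to 1840 CPM, Gfap from 22.9 to 63.5 CPM, and Fgfr3 had a spread of 0.119 that became 0.0652 without m57. Microglia genes lay at percentile 87.6, with C1qb between 19.9 and 52.5 CPM. Vascular genes lay at percentile 37.3, which was 71.6 without m61, 19.57 without m49, 22.82 without m89, 24.3 without m101 and 21.61 on unscaled totals. Pdgfrb, a pericyte gene, varied least of that list (21.7 to 28.5 CPM, spread 0.0761), Rgs5 ranged from 85.4 to 122 CPM and Kdr from 5.45 to 12.5 CPM. Red blood cell genes had a median spread of 0.424, at percentile 96.9, and 90.7 without m89 or 93.1 without m115. Hbb-bs, a beta globin gene, ranged from 15.0 CPM in m115 to 47.9 CPM in m61, and Hbb-bt from 1.35 to 5.41 CPM. Hba-a2 ranged from 0.689 to 7.57 CPM. The globin genes have near-identical copies, so the split of reads between Hba-a1 and Hba-a2 or Hbb-bs and Hbb-bt is uncertain.

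Markers of the ventricle wall next to the striatum differed strongly between libraries. Neuroblast and dividing-cell genes of the subventricular zone had a median spread of 0.449, at percentile 100, with the lowest score in m57 (−1.25) and the highest in m47. Dcx, the doublecortin gene, ranged from 27.7 CPM in m44 to 92.8 CPM in m47, and Top2a, a gene of dividing cells, from 0.520 CPM in m57 to 18.3 CPM in m47. Dlx1 ranged from 20.9 to 85.6 CPM, Sox11 from 33.1 to 98.1 CPM, Sox4 from 21.5 to 74.9 CPM, Cd24a from 10.3 to 45.3 CPM, Dlx2 from 7.89 to 32.5 CPM and Igfbpl1 from 2.05 to 20.5 CPM. Of 11 choroid plexus and ependyma genes 4 passed the filter, at percentile 98.7. Foxj1, the regulator of motile cilia, reached 16.7 CPM in m115, 14.4 in m47 and 8.08 in m49, and lay between 2.27 and 6.69 CPM in the other libraries. Ccdc153, a cilia gene, ranged from 0.0245 CPM in m74 to 7.58 CPM in m115, Clic6 from 10.4 to 24.5 CPM and Kl from 3.33 to 6.86 CPM. Ttr, the abundant transthyretin gene of the choroid plexus, was at most 0.224 CPM.

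Cortical glutamatergic genes had a median spread of 0.266, at percentile 96.7, which was 68.3 without m61 and 91.5 without m47. Slc17a7, a vesicular glutamate transporter gene, was abundant in every library, from 636 CPM in m115 to 2118 CPM in m61. Fezf2 ranged from 4.99 to 23.8 CPM and Neurod2 from 45.4 to 82.6 CPM. Septal, hypothalamic and thalamic genes lay at percentile 40.8, which was 18.4 without m74, 27.1 without m49 and 64.93 without m61, with Zic1 between 20.1 and 56.5 CPM and Nkx2-1 between 2.47 and 4.19 CPM.

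Immediate early genes had a median spread of 0.329, at percentile 99.9, and 92.5 without m89, the library with the highest score (1.13). In m89 Fos reached 26.9 CPM and Arc 109 CPM, against medians of 5.61 and 29.1 CPM. Egr1 ranged from 89.5 to 232 CPM and Egr2 from 0.0345 to 3.90 CPM, and the spread of Dusp1 was 0.214, or 0.0440 without m89. Interferon-induced genes had a median spread of 0.470, at percentile 99.7, with a score from −0.60 in m57 to 0.93 in m73. Isg15 was at 7.32 CPM in m73, and its spread of 0.661 became 0.348 without that library. Ifit3 ranged from 2.98 to 11.03 CPM, Oasl2 from 1.60 to 7.91 CPM, Irf7 from 1.33 to 6.50 CPM, Bst2 from 1.11 to 3.92 CPM and Ifi27 from 28.9 to 48.8 CPM. Glucocorticoid-induced genes lay at percentile 78.4, where Plin4 ranged from 0.0443 to 6.89 CPM, Tsc22d3 from 49.5 to 77.7 CPM and Fkbp5 from 43.0 to 71.6 CPM. Heat shock and unfolded protein response genes lay at percentile 50.5, which was 11.58 without m74 and 28.5 without m49, with Hspa8 between 565 and 954 CPM and Hsph1 at a spread of 0.115. Hspa1b, which has a near-identical neighbour in Hspa1a, ranged from 1.22 to 3.87 CPM.

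Clock repressor and output genes lay at percentile 97.8 and the clock activators at 93.1, which was 96.3 without m61. Per3 ranged from 13.7 CPM in m61 to 74.7 CPM in m89 and Tef from 377 to 540.3 CPM. Of the activators, Clock ranged from 53.5 to 107 CPM, Npas2 from 29.2 to 66.9 CPM, and Arntl varied least (22.0 to 31.5 CPM, spread 0.110).

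Mitochondrially encoded genes had a median spread of 0.321, at percentile 99.96, with the highest level of mt-Cytb in m61 (18850 CPM) and the lowest in m74 (7094 CPM). Its spread of 0.277 became 0.158 without m61. The gene mt-Co3 was counted at a median of only 1.62 CPM, against 7691 CPM for mt-Co1. The reason was not tested, so the mitochondrial shares given above may leave out reads and be too low. Nuclear genes of oxidative phosphorylation lay at percentile 61.4, with Atp5b between 1251 and 1892 CPM, Cox6a1 between 165 and 434 CPM and Sdha at a spread of 0.0786. Ribosomal protein genes had a median spread of 0.247, at percentile 99.5, with a score from −0.36 in m115 to 0.72 in m61. Rpl4 ranged from 448 to 832 CPM and Rps18 from 36.8 to 90.7 CPM. The only RNA without a poly(A) tail past the filter, Rn7sk, ranged from 1.75 CPM in m115 to 8.81 CPM in m74, at percentile 86.9.

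The libraries differed in the level of long against short transcripts, and several of these gene groups moved with that difference. The median log2 deviation of the longest 10% of genes minus that of the shortest 10% was −0.64 in m61, −0.48 in m83, −0.48 in m74 and −0.28 in m101. It was −0.10 in m49, −0.08 in m44, 0.24 in m73, 0.25 in m89, 0.42 in m47, 0.50 in m115 and 0.50 in m57. The ribosomal protein score fell along this measure (r = −0.93, rho = −0.94, permutation adjusted p = 0.00085 for r and 0.00102 for rho; r = −0.91 without m57 and m115). The nuclear oxidative phosphorylation score did likewise (r = −0.95, rho = −0.95, permutation adjusted p = 0.00034 and 0.00102; r = −0.95 without the same libraries). Of 34 lists 4 passed the adjusted p of 0.05 by r, the others being Rn7sk (r = −0.81, rho = −0.82, permutation adjusted p = 0.0286 and 0.0315) and microglia (r = −0.76, rho = −0.71, permutation adjusted p = 0.0449 and 0.0763). The r without m57 and m115 was −0.78 for Rn7sk and −0.87 for microglia. By rho 4 further lists passed and microglia did not: clock activators (permutation adjusted p = 0.0315), strain-variable genes (0.0315), heat shock genes (0.0328) and dorsolateral genes (0.0412). The length measure was chosen after the data were seen. It holds members of these lists, since 5 of 10 ribosomal protein and 4 of 13 oxidative phosphorylation genes were among the shortest 10%. With the members of each list taken out of the measure r was still −0.93 and −0.95. Random lists of the same transcript lengths also fell along it, with a median r of −0.81 and −0.79, and 12.61% and 5.35% of them had an r as low. For Rn7sk and microglia 34.45% and 17.77% of the random lists did, so none of the 4 lists fell further than 95% of lists of its transcript lengths.

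**Figure D2:**
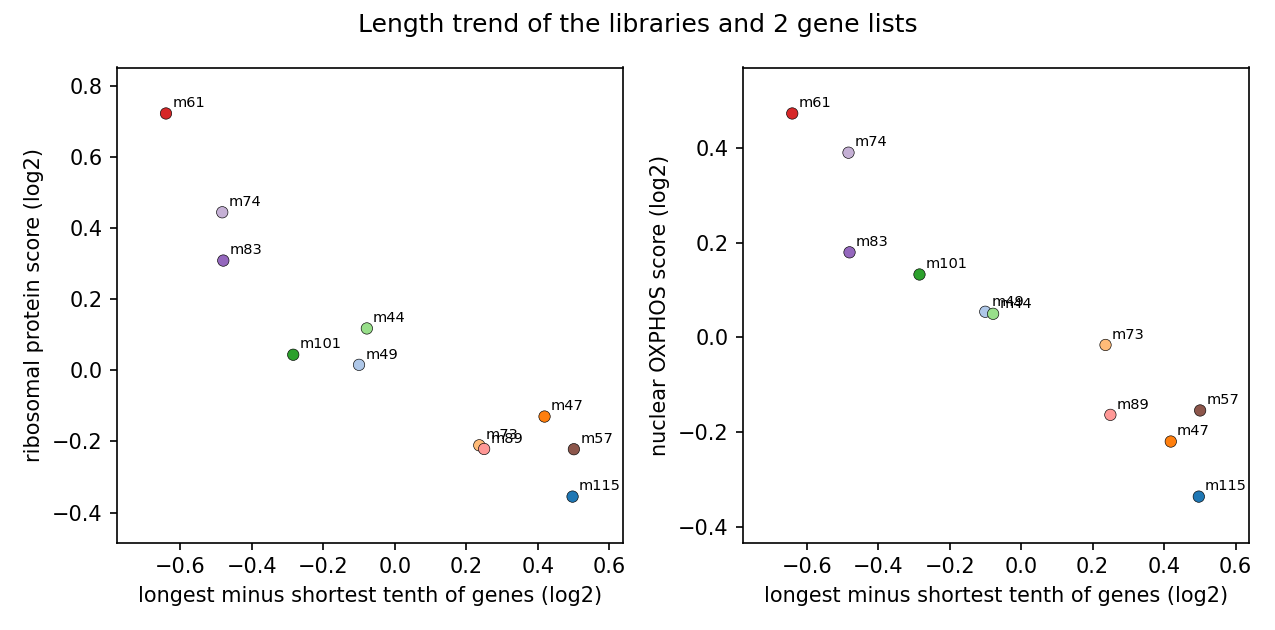
Score of the ribosomal protein genes (left) and of the nuclear oxidative phosphorylation genes (right), in log2 units, against the log2 deviation of the longest 10% minus the shortest 10% of genes. Each labelled point is 1 of the 11 libraries. Both scores were highest in m61, where the length measure was −0.64, and r was −0.93 and −0.95.

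Y-linked genes were present in all 11 libraries, with Eif2s3y between 25.3 and 58.7 CPM, Ddx3y between 21.4 and 72.3 CPM, Kdm5d between 16.9 and 39.1 CPM and Uty between 3.90 and 20.2 CPM. Xist, the RNA of the inactive X chromosome, had a median of 0.449 CPM and reached 10.3 CPM in m89 and 4.79 CPM in m101. It had no count in m74, where 3 counts would be 0.0735 CPM. The sex-linked list lay at percentile 99.4. Of the genes known to differ between mouse strains 5 passed the filter, at percentile 99.0, which was 45.0 without m74. Gabra2, a GABA receptor gene, was at 67.5 CPM in m74 and between 169 and 292 CPM in the other libraries, and its spread of 0.347 became 0.172 without m74. Wdfy1 ranged from 13.3 to 49.6 CPM, Glo1 from 78.2 to 132 CPM and Disc1 from 0.0887 to 2.12 CPM. Nnt had a median of 0.269 CPM and Entpd4 was at most 0.0220 CPM.

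Genes near Rarb on chromosome 14 varied about as much as random lists (median spread 0.163, percentile 46.0). Thrb, the thyroid hormone receptor beta gene, ranged from 24.8 to 53.5 CPM, Top2b from 65.6 to 133 CPM, Nr1d2 from 62.5 to 181 CPM and Ngly1 from 17.1 to 29.8 CPM. Oxsm ranged from 7.91 to 12.9 CPM, Nkiras1 from 69.8 to 109 CPM, Ube2e1 from 63.5 to 91.7 CPM and Ube2e2 from 49.5 to 79.7 CPM. Rpl15 had a spread of 0.173, or 0.0736 without m61. Gm8420, a processed pseudogene on chromosome 1, shares 37.6% of its stretches of 25 bases with Rpl15. It lay between 1.81 and 4.48 CPM in m115, m49, m47, m44, m61 and m57. In m73, m101, m89, m83 and m74 it lay between 0 and 0.207 CPM. Whether a variant near Rarb sets this split was not tested.

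Over the 15373 genes past the filter the spread had a median of 0.201, with quartiles of 0.142 and 0.299, and 1045 genes (6.80%) reached 0.5. In all, 21 of the 34 lists lay at or above percentile 95 and 0 at or below percentile 5. The genes of largest spread were mostly pseudogenes and single-exon loci still to be tested experimentally, for which the assignment of reads is uncertain where a near-identical copy or an overlapping gene exists. They were led by Gm14094 (spread 2.05), Gm10263 (1.97), A930036I15Rik (1.94), Gm6166 (1.89), Gm36989 (1.84) and Rpsa-ps10 (1.84). Among protein-coding genes, Plcxd3, a phospholipase-like gene, ranged from 0 to 11.9 CPM and Styx from 0 to 1.85 CPM. Styx shares 31.6% of its stretches of 25 bases with Gm14698 on chromosome X, so the assignment of its reads is uncertain too. The smallest estimates, among them those for Zscan12, Nup43, Irak4, 2810407A14Rik and 9130023H24Rik, were 0.00988, the lower bound of the estimate. Zscan12 stayed between 8.46 and 10.4 CPM.

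**Figure D3:**
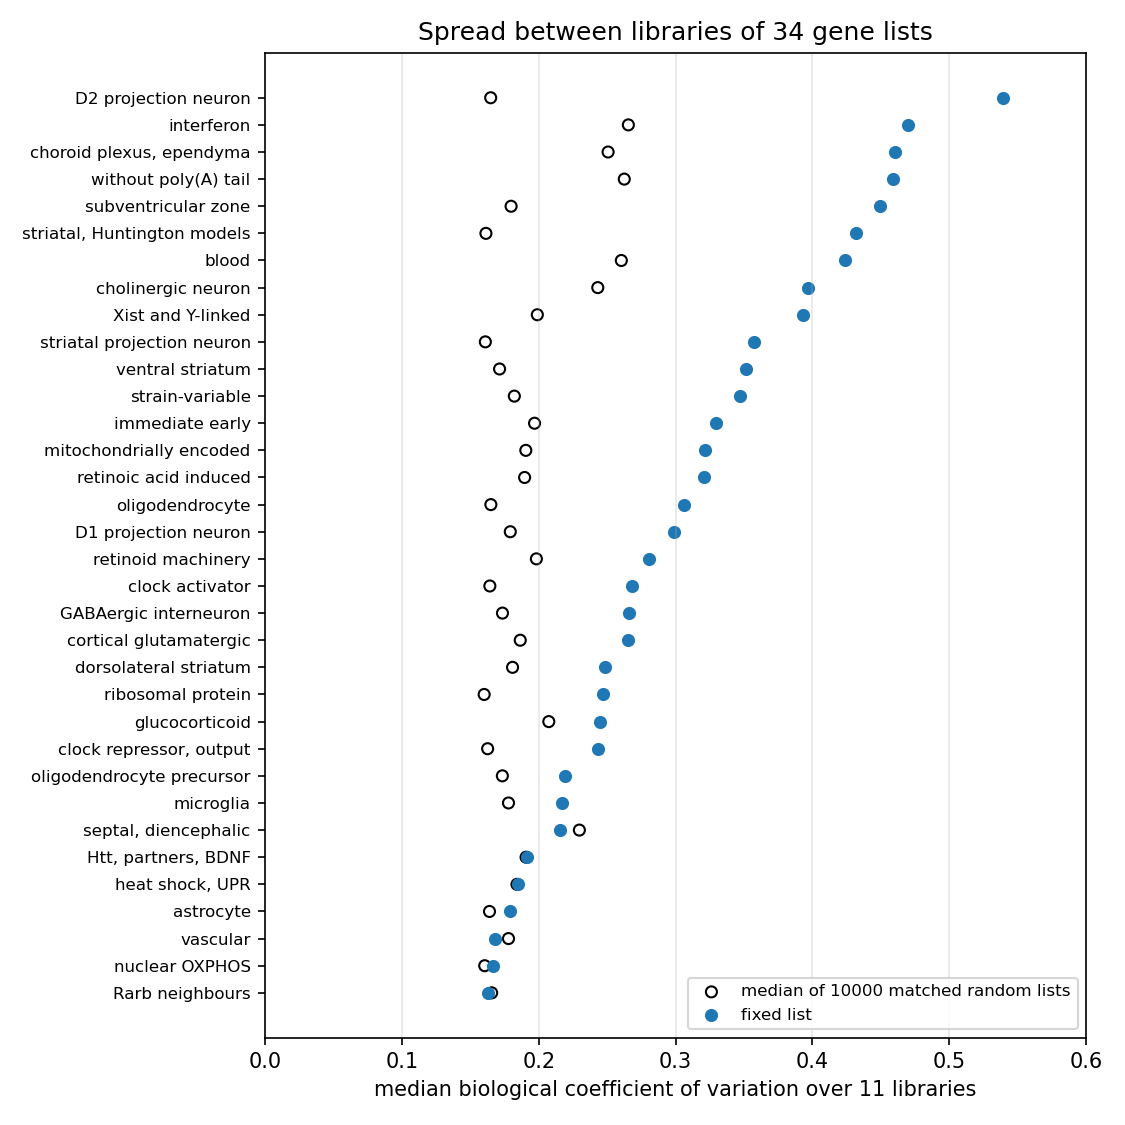
Median biological coefficient of variation of each of the 34 fixed gene lists over the 11 libraries (filled points) and the median of 10000 random lists of the same size and expression (open points). The indirect-pathway list was the highest at 0.540, and the genes near Rarb were the lowest at 0.163.

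The first principal component of the 500 most variable genes held 48.0% of the variance, the second 12.0% and the third 10.0%. Scores on the first were −19.6 in m57, −17.0 in m47, −16.7 in m73, −14.8 in m115 and −6.16 in m89. They were 5.64 in m74, 6.79 in m44, 10.3 in m49, 11.6 in m101, 16.6 in m83 and 23.4 in m61. Lmbrd2 (0.379 CPM in m101 to 35.8 CPM in m57), Plcxd3, Gm38020, Gm44560 and ENSMUSG00000109836 led the low end, and the copies Atp6v0c-ps2, Gm10260, Gm10263 and Gm13443 with Gm44675 led the high end. On the second component, Tuba1c, Ccdc153, Gm6682, Top2a and Dnali1, an axonemal dynein gene, led the high end, where m49 (11.7), m115 (11.7) and m47 (9.17) scored highest. The low end was led by Rpsa-ps10, Gm5148, Tnnt1, Tnni3 and Gm6916. The troponin gene Tnnt1 reached 26.3 CPM in m57, against a median of 1.86 CPM, and Tnni3 reached 13.4 CPM in m57, against 0.862 CPM.

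Relations between gene groups were computed over the 11 libraries for 16 pairs fixed beforehand, with Benjamini-Hochberg adjustment over the 16, and 4 passed an adjusted p of 0.05 by r among the 14 without separate clusters. The red blood cell and vascular scores rose together (r = 0.87, permutation p = 0.00042, adjusted p = 0.00672; rho = 0.87, permutation p = 0.00096, adjusted p = 0.008). Without m115 and m74 r was 0.91, and with the length trend removed from every library it was 0.75 (permutation adjusted p = 0.026). With the median over members in place of the mean it was 0.44 (permutation adjusted p = 0.28), and the call was lost. Microglia and vascular scores were related at r = 0.79 (permutation p = 0.00424, adjusted p = 0.0206) and rho = 0.70 (permutation p = 0.0208, adjusted p = 0.0476). That r was 0.58 without m61 and m47, 0.65 (permutation adjusted p = 0.081) without m61 alone, and 0.72 (permutation adjusted p = 0.0354) with the length trend removed. It was 0.56 (permutation adjusted p = 0.163) on unscaled totals and 0.69 (permutation adjusted p = 0.15) with the median over members. Clock activators and clock repressors rose together (r = 0.77, permutation p = 0.00645, adjusted p = 0.0206; rho = 0.83, permutation p = 0.00255, adjusted p = 0.0102). Here r was 0.64 without m57 and m74, 0.68 (permutation adjusted p = 0.106) without m57, 0.73 (permutation adjusted p = 0.0662) without m61, and 0.80 (permutation adjusted p = 0.026) with the length trend removed. With the median over members and with members at unit variance it was 0.52 (permutation adjusted p = 0.167 and 0.172). The clock repressor score was 0.10 to 0.24 in m44, m89, m83 and m57, whose codes lie between NSZR9 and NSZR14. It was −0.23 to −0.06 in the other libraries, with m61 (NSZR12) at −0.11. The activator score did not split so, with 0.25 in m47 and −0.09 in m61. A part of this r from genotype or from the ranges of codes cannot be told apart.

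Rarb rose with the score of the striatal projection neuron genes, at r = 0.77 (permutation p = 0.00604, adjusted p = 0.0206) and rho = 0.85 (permutation p = 0.00124, adjusted p = 0.008). Without m74 and m44 r was 0.60, and with the length trend removed it was 0.68 (permutation adjusted p = 0.0378). The call was lost by a small margin without m44 (r = 0.71, permutation adjusted p = 0.0551), m61 (0.79, 0.054), m74 (0.70, 0.059) or m57 (0.73, 0.0553), on unscaled totals (0.73, 0.0567) and with the median over members (0.74, 0.0708). The projection neuron scores had their largest gap, 42% of their range, between 5 libraries and the other 6, short of the 50% set for separate clusters. With that limit lowered to 0.4 of the range, an alternative added after the data were seen, r with Rarb within these 6 was 0.85 (exact permutation p = 0.0292, adjusted p = 0.0681 over 7 relations; rho = 0.71, exact permutation p = 0.136, adjusted p = 0.317). The other 5 were too few for an r. The library codes of these 5 lie between NSZR9 and NSZR14, and those of the 6 between NSZR1 and NSZR7. The labels do not assign the genotypes that the design names. The r over all 11 libraries therefore cannot be told apart from a difference between genotypes or between these ranges of codes. Rarb and the other retinoic acid induced genes, with Rarb left out of that list, were not related at this number of libraries (r = 0.34, permutation p = 0.304, adjusted p = 0.406; rho = 0.39, permutation p = 0.236, adjusted p = 0.321; r = 0.11 without m74 and m44). That r was 0.15 without m44 alone and 0.58 (permutation adjusted p = 0.108) with the GC trend removed.

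**Figure D4:**
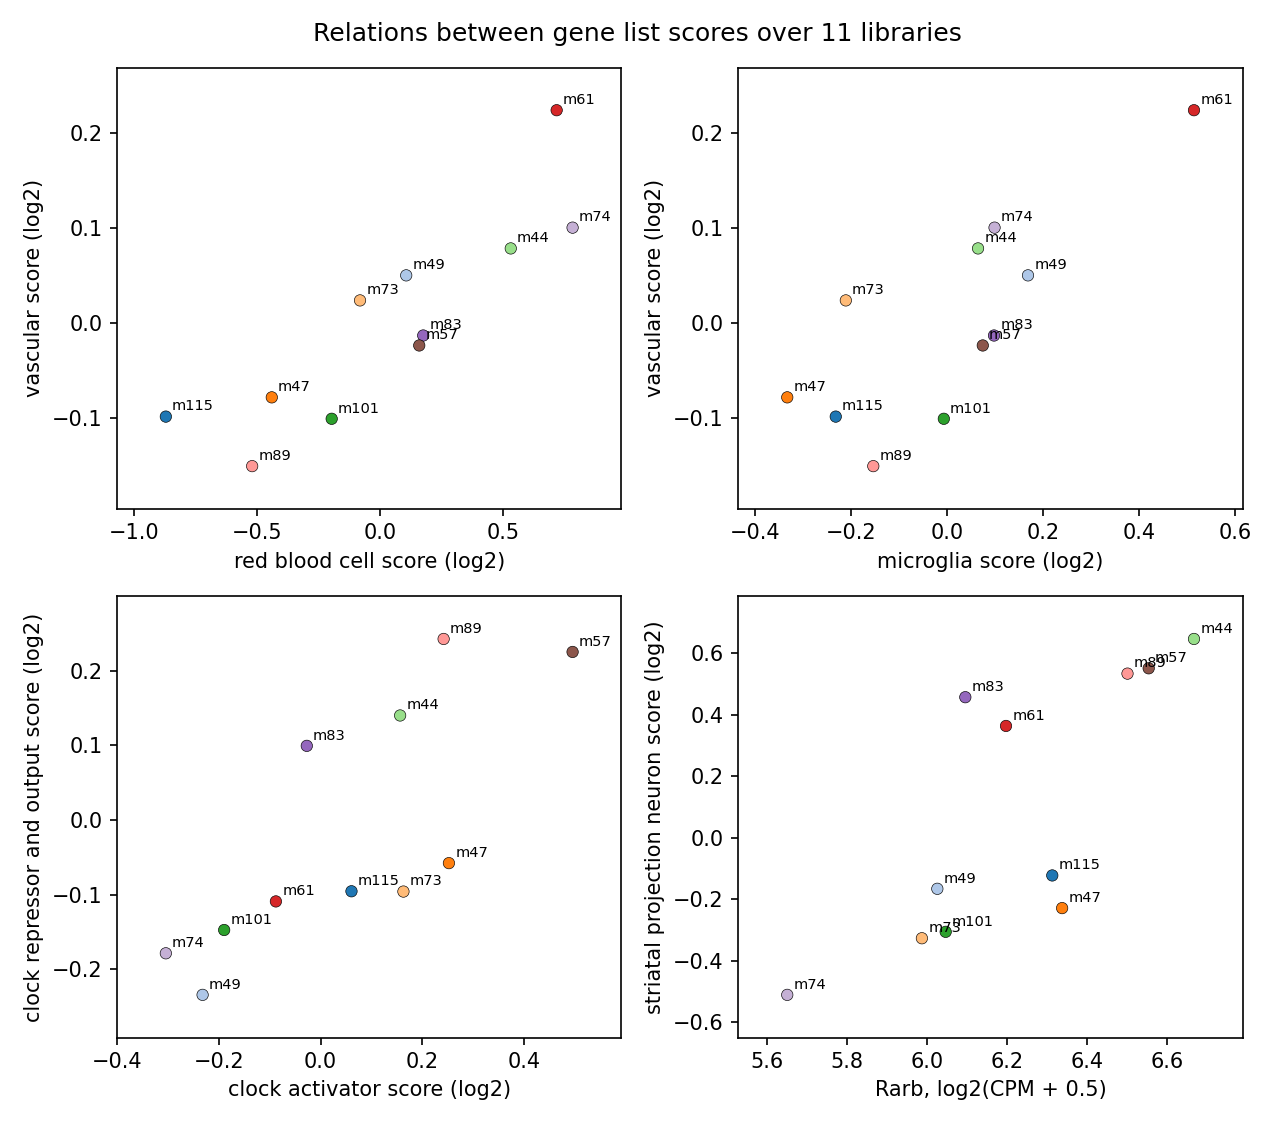
The 4 relations that passed the adjusted p of 0.05 by r, with each labelled point 1 of the 11 libraries. Scores are mean log2 deviations from each gene's median, and Rarb is log2(CPM + 0.5); r was 0.87, 0.79, 0.77 and 0.77 from the upper left panel to the lower right. In the panel of Rarb the projection neuron scores leave a gap of 42% of their range.

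The projection neuron score had r = 0.68 with the oligodendrocyte score (permutation p = 0.0241, adjusted p = 0.0551; rho = 0.52, permutation p = 0.107, adjusted p = 0.19; r = 0.69 without m44 and m57), and r was 0.84 (permutation adjusted p = 0.0244) without m74. With the astrocyte score r was 0.68 (permutation p = 0.0236, adjusted p = 0.0551) and rho 0.77 (permutation p = 0.00772, adjusted p = 0.0247), with r = 0.70 without m44 and m57, 0.75 (permutation adjusted p = 0.0374) without m44 alone and 0.74 (permutation adjusted p = 0.0343) without m74. Neither relation passed by r. The gap in the projection neuron scores applies to them too, and within the 6 libraries below it the sign of r with the oligodendrocyte score turned, to −0.87 (exact permutation p = 0.0278, adjusted p = 0.0681; rho = −0.71, exact permutation p = 0.136, adjusted p = 0.317). The positive r over all 11 libraries therefore did not hold below the gap. With the astrocyte score r within these 6 was 0.22 (exact permutation p = 0.704, adjusted p = 0.704; rho = 0.49, exact permutation p = 0.356, adjusted p = 0.58). Oligodendrocyte and precursor scores had r = 0.64 (permutation p = 0.0334, adjusted p = 0.0669) and rho = 0.70 (permutation p = 0.0199, adjusted p = 0.0476), with r = 0.66 without m47 and m49 and 0.72 (permutation adjusted p = 0.0496) without m49 alone. With the length trend removed, an alternative added after the data were seen, these 3 relations and that of astrocytes with microglia passed (permutation adjusted p from 0.026 to 0.0354). Mitochondrially encoded and nuclear oxidative phosphorylation genes had r = 0.18 (permutation p = 0.599, adjusted p = 0.684; rho = 0.38, permutation p = 0.246, adjusted p = 0.321), which became 0.83 (permutation adjusted p = 0.0244) without m74, −0.31 without m61 and 0.61 without m74 and m61. It was −0.29 (permutation adjusted p = 0.412) with the length trend removed, 0.57 (permutation adjusted p = 0.108) with the GC trend removed, 0.28 with the median over members and 0.03 on unscaled totals. The projection neuron score had r = 0.53 with immediate early genes (permutation p = 0.0714, adjusted p = 0.114; rho = 0.38, permutation p = 0.248, adjusted p = 0.321; r = 0.73 without m44 and m57), and −0.47 within the 6 libraries below the gap (exact permutation p = 0.354, adjusted p = 0.619; rho = −0.43, exact permutation p = 0.419, adjusted p = 0.58). With cortical genes r was −0.02 (permutation p = 0.96, adjusted p = 0.96; rho = −0.01, permutation p = 0.989, adjusted p = 0.989; r = 0.29 without the same pair), and −0.37 below the gap (exact permutation p = 0.464, adjusted p = 0.65; rho = −0.37, exact permutation p = 0.497, adjusted p = 0.58), and the r over all libraries ran from −0.21 (without m89) to 0.28 (without m44) with each left out. With septal and diencephalic genes r was 0.09 (permutation p = 0.788, adjusted p = 0.84; rho = 0.37, permutation p = 0.261, adjusted p = 0.321; r = 0.14 without the same pair), and 0.86 below the gap (exact permutation p = 0.0264, adjusted p = 0.0681; rho = 0.94, exact permutation p = 0.0167, adjusted p = 0.117), and the r over all libraries ran from −0.20 (without m74) to 0.25 (without m47) with libraries left out. Ventral and dorsolateral striatal scores had r = 0.29 (permutation p = 0.38, adjusted p = 0.468; rho = 0.20, permutation p = 0.556, adjusted p = 0.593; r = 0.18 without m74 and m73), which was −0.03 without m74, 0.49 without m73 and 0.19 without m57. The dorsolateral scores had a gap of 49% of their range, and r was −0.22 within the 9 libraries above it (exact permutation p = 0.563, adjusted p = 0.657; rho = −0.13, exact permutation p = 0.744, adjusted p = 0.744). Astrocyte and microglia scores had r = 0.47 (permutation p = 0.149, adjusted p = 0.216; rho = 0.28, permutation p = 0.401, adjusted p = 0.459; r = 0.30 without m61 and m101), which was 0.23 without m61, 0.17 on unscaled totals and 0.25 with the median over members.

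The indirect-pathway scores fell into separate clusters by a small margin, with a gap of 51.4% of their range against the limit of 50%, so no r over all libraries is given for them with the direct-pathway genes or with Rarb. Within the cluster of 6 libraries r was 0.53 with the direct-pathway genes (exact permutation p = 0.287, adjusted p = 0.304; rho = 0.83, exact permutation p = 0.0583). With Rarb it was 0.53 (exact permutation p = 0.304, adjusted p = 0.304; rho = 0.54, exact permutation p = 0.297). The total count of a library was not related to any of the 34 list scores after adjustment, the smallest permutation adjusted p being 0.568, for the list of Htt and its partners (r = 0.70, permutation p = 0.0167; rho = 0.77, permutation p = 0.00752, adjusted p = 0.256; r = 0.54 without m61 and m49). Without m57, 1 list passed.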

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

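The tests with GC or length trends removed, with a smaller gap for clusters, and of the length measure without list members and beside random lists were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because the labels put no library in a group. On unscaled totals the relation of microglia with vessels fell to r = 0.563 and that of Rarb with projection neuron genes to 0.726, both no longer past the adjusted threshold. With the median over members, r was 0.690 for microglia with vessels, 0.440 for red blood cells with vessels, 0.525 for the clock lists and 0.745 for Rarb with projection neuron genes, none past it. With members at unit variance the clock lists gave 0.525, no longer past it, and projection neuron with astrocyte genes 0.700, now past it. That last relation also passed with GC trends removed (0.691) and with length trends removed (0.673). With length trends removed, projection neuron with oligodendrocyte genes (0.756), oligodendrocytes with precursors (0.792) and astrocytes with microglia (0.704) passed too. No relation changed its call with DESeq2 size factors, a pseudocount of 5 or members at a median count of 100 or more. With clusters at a gap of 0.4 of the range, r within the larger cluster turned for projection neuron with oligodendrocyte genes (−0.866) and immediate early genes (−0.466) and for ventral with dorsolateral genes (−0.218), and was 0.851 for Rarb with projection neuron genes, not past the threshold with 6 libraries.

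With each library left out, r ranged from 0.650 to 0.841 (highest without m74) for projection neuron with oligodendrocyte genes, 0.614 to 0.753 (without m44) for the former with astrocytes, 0.559 to 0.723 (without m49) for oligodendrocytes with precursors, 0.650 (without m61) to 0.857 for microglia with vessels, −0.310 (without m61) to 0.828 (without m74) for mitochondrially encoded with nuclear genes, 0.680 (without m57) to 0.825 for the clock lists and 0.698 (without m74) to 0.855 for Rarb with projection neuron genes. Red blood cells with vessels stayed past the threshold, at 0.842 to 0.893. The number of lists related to the library total was 0 to 1 (without m57).

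The number of genes with a spread of 0.5 or more was 10534 without the filter and 294 at a median count of 100 or more, where fewer genes were tested; it was 822 to 1084 under the other alternatives and 835 (without m61) to 1063 with libraries left out. Genes in separate clusters numbered 12 at a gap of 0.6, 35 at a median count of 100 or more and 49 with DESeq2 size factors. The first component held 39.2 to 51.6% of the variance. List percentiles left the upper 5% for cortical genes (87.3) and clock repressors (94.5) on unscaled totals and for strain-variable genes (93.9) by the moment estimate. The causes of these changes were not tested. Depth limits genes near the floor of 3 counts, such as Cyp26c1.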

Other observations

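The tests of shared reads, of simulated counts, of parent gene positions, of length and GC content together and of the share of projection neurons were chosen only after the results they bear on were seen. The labels give no genotype per library, so genotype, which the design names, was not tested for any pattern and stays open throughout. They also give numbered library codes, from NSZR1 to NSZR14, without saying what the numbers stand for. An effect of their order was not tested.

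Of 15373 genes, 57 (0.371%) had libraries in separate clusters, against 18 to 39 (median 26.5) in 20 simulated sets. The same 13 genes were higher in m115, m47, m73, m89 and m57, among them the cadherin gene Pcdh17, Klhl7, Erbin, Snx13 and Cpeb2. In these 5 libraries the length measure was above 0 (0.24 to 0.50) and the score on the first component of the 500 most variable genes below 0 (−19.6 to −6.16), and in the other 6 the measure was at or below −0.08 and the score at or above 5.64. The striatal genes Adora2a, Gpr6, Pdyn and Scn4b, with Ier5l, were higher in m44, m61, m89, m83 and m57. These 5 libraries have the codes NSZR10, NSZR12, NSZR13, NSZR14 and NSZR9. The 6 lower libraries have the codes NSZR1, NSZR2, NSZR3, NSZR5, NSZR6 and NSZR7, so this split follows the numbering without exception. Rgs9, a further striatal gene in separate clusters, split otherwise, at 236 to 268 CPM in m44, m89, m83 and m57 and 120.9 CPM in m61, against 82.79 to 124 CPM in the other 6. Of the 34 list scores 2 met the same rule. The score of striatal genes of Huntington disease models was 0.92 in m44, 0.80 in m83, 0.80 in m89, 0.74 in m57 and 0.65 in m61. It was −0.19 in m101, −0.23 in m115, −0.26 in m47, −0.26 in m49, −0.26 in m73 and −0.40 in m74. The indirect-pathway score was 1.10 in m44, 1.04 in m83, 1.01 in m61, 0.80 in m89 and 0.73 in m57. It was −0.03 in m49, −0.11 in m115, −0.11 in m47, −0.17 in m101, −0.27 in m74 and −0.36 in m73.

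The gap in the score of striatal genes took 63.3% of its range. It was 62.06% with each library's GC trend removed and 62.84% with every library thinned to the smallest total, so neither step removed it. Thinning evens out the totals only and cannot undo differences already present in the libraries. A lower share of projection neurons alone, with the mix of other cells unchanged, would move alike the genes that only these neurons make. It would also raise markers of every other cell type. The 16 other genes of the projection neuron lists moved by a median of 0.4294 log2 units per unit of the striatal score. With each library left out this median was 0.377 to 0.463. The slopes ran from −0.29 for Eya1 to 1.40 for Gpr6. Pde1b moved by 1.00, Rasd2 and Pdyn by 0.92, Bcl11b by 0.26, Sfxn1 by −0.09 and Sp9 by −0.15. Whether each of the 16 is made only by these neurons was not tested, so their slopes cannot decide the question. Of 12 lists of other cell types 7 rose with the score whichever library was left out, among them oligodendrocytes by 0.55 (0.477 to 0.669). Of the others 1 fell, the subventricular zone list (−0.38). The rise of these 7 lists argues against a change in that share alone as the whole cause of the split. Punches that differed in several cell types together could give such slopes and were not tested. They stay open, as does a part for the share of projection neurons. Genotype stays open too, as does a difference in processing that follows the library codes, which was not tested.

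The first component over all 15353 genes with a known length and GC content followed transcript length (rho = −0.58 across genes, which are not independent replicates) and GC content (rho = 0.41). Over the libraries its score had r = −0.96 with the length measure, which is made from genes that the component also holds. Thinning to the smallest total changed the variance of this component by −0.4479%, as a reduction, so the gradient did not need unequal totals. Thinning cannot undo differences already present in the libraries, so other effects that go with depth were not tested. Removing each library's GC trend lowered that variance by 14.26%, which argues against GC content as the whole cause. Removing the length trend lowered it by 27.26% and the joint trend by 33.73%. Both lie between the 20% set as too little and the 50% set as enough, so a length bias, as from RNA fragmentation or bead selection, cannot be told apart from a difference in the tissue that follows length; it may account for part of the gradient.

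In 9 genes in separate clusters the log2 range was at least 4, and 88.89% of them were annotated pseudogenes, against 1.63% of all genes past the filter. At most 3 such genes arose in any of 20 sets simulated with each gene's mean and spread. This argues against counting noise together with spread that forms no clusters. Reads shared with a parent gene are a candidate source, and a variant in the parent that moves reads to or from the copy may set the split. Copies here are genes in separate clusters that share at least 30% of their stretches of 25 bases with a protein-coding gene elsewhere. That other gene is called the parent. Which gene of a pair is the copy was not tested, as for Styx, whose parent by this rule is Gm14698. Among 15 copies, 10 pairs split the libraries alike and all 10 had parents within 10 Mb, of 15 such pairs among 105 (permutation of parents, p = 0.0014); Gm10260, Gm13443, Hmga1b, Atp6v0c-ps2 and Gm9825, lower in m47, m73 and m57, have the parents Rps18, Glo1, Hmga1, Atp6v0c and Rnps1, all on chromosome 17 between 24163866 and 33956001. These 5 genes make up all 10 pairs, and a further copy, Gm10263, whose parent Rps28 lies in the same stretch, split otherwise, with 0 CPM in m115. By the genes' own positions only 1 pair lay within 10 Mb and 0 such pairs split alike, too few to decide.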
